A study of Mus musculus with 12 samples.

How the data were processed

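Gene expression was measured by 3′ mRNA sequencing in 12 libraries of R1 mouse embryonic stem cells, a male line of strain 129. Per the labels, 3 libraries came from cells in serum with LIF at day 0 (primed), 3 from cells after 6 days of 2i, and 3 each from cells after 6 days of 2i with 25 or 50 µM of an MRE11 inhibitor whose name is not given in the sources used here. Per the labels' protocols, total RNA was made into libraries with QuantSeq 3′ mRNA-seq, a kit that primes with oligo-dT, so that counts come from the 3′ ends of transcripts, and no adjustment for gene length was made.

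The values used were the raw counts per gene that the authors deposited, with 1 table per library. FastQC, STAR and DESeq2 1.32.0 and the mouse build GRCm38 are named in the submitters' processing notes. The STAR version, the tool that counted reads, the annotation release, the strand setting and any use of molecular identifiers are not given in the sources used here. Genes that overlap, or that share reads with near-identical copies, are therefore called uncertain where they are described. Each table held 56805 features. Of these, 56691 were mouse gene IDs, and 114 were spike-in features, which had 2 counts over all libraries and were left out. A table of the whole series held identical values and was not used, and 0 columns of per-sample values were left unmapped. Symbols were found for 52073 of the IDs, which carried 98.4% of counts; the 4618 IDs without a symbol stayed in the fits under their IDs. Gene positions are those of the GRCm38 annotation.

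Library totals ranged from 5894561 to 7060126 counts. Groups and replicate numbers were taken from the labels, which do not say whether replicates were separate cultures. Chi-square tests of counts, divided by their degrees of freedom, gave 2.64 to 13.2 between replicates of a group, so no library was treated as a duplicate.

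Differential expression was tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16, with TMM normalisation, the filterByExpr low-count filter, robust dispersion and all 12 libraries in 1 fit. This left 13230 genes. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 with no fold minimum. The SE of a log2 fold change is its size divided by the square root of the F value. Comparisons were 2i against primed, each dose against 2i, 50 against 25 µM, and each dose against primed. Log2 CPM used a prior count of 2, and principal components used the 1000 most variable genes. A fold against a group with no counts was computed from a floor of 3 counts over the group. Count ratios have exact 95% intervals. The intervals of count ratios and the floors cover counting error only.

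Gene lists were tested with camera on voom values in limma 3.58.1, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 30 lists within a comparison. Only members that passed the low-count filter were measured. For 2-cell-like genes that left 9 of 21, for mesoderm markers 8 of 20, for neuroectoderm markers 9 of 20 and for fibroblast markers 11 of 21. The lists, 764 distinct genes with 25 on more than 1 list, were written before the data were examined, as were the tests of the comparisons, the rule for named genes and the alternatives, except those stated below as chosen after seeing the data; the closing section names its own tests chosen after the result was seen. They covered naive, general, and primed and formative pluripotency; targets of ERK, Wnt, LIF/STAT3, p53, NRF2, the aryl hydrocarbon receptor and the integrated stress response; DNA methylation machinery, germline, imprinted and 2-cell-like genes and Polycomb subunits; DNA replication, the MRE11 complex with fork protection and break repair, and G2/M; interferon-stimulated genes; chaperones, cholesterol, glycolysis, nuclear and mitochondrial respiratory genes and ribosome biogenesis; and markers of mesoderm, endoderm, neuroectoderm, trophoblast and fibroblasts.

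Genes were named by rule. The first part took the 6 largest rises and 6 largest falls per comparison, or 4 and 4 between the doses and none for inhibitor against primed. These had an adjusted p below 0.05, a mean log2 CPM of at least 3, no predicted-gene name, and every library of one group above every library of the other, which chance gives in 10% of genes. The second part was a fixed set of anchor genes, among them Mre11a, Rad50, Nbn, Nanog, Tfcp2l1, Dppa3, Otx2, Dusp6 and Axin2. The third part took up to 4 members with the smallest p of each called list and 2 of each other list. Genes whose call was lost without 1 or more libraries are described only where a list or comparison calls for them, with those values. Some genes taken by the rule are not reported here.

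The shift of 2i-responsive genes was measured with each 2i library held out in turn. Genes with an adjusted p below 0.05 and an absolute log2 fold change of at least 1 were chosen by edgeR from the other 2i libraries against primed. The median difference in log2 CPM between the inhibitor group and the held-out library, signed by the 2i response, was then averaged over the 3. The naive minus primed index is the mean log2 CPM of the naive list minus that of the primed and formative list, compared by exact two-sided permutation tests. Overlaps are given beside those of independent lists and of 20 simulations of unchanged groups against the same controls.

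Same-numbered libraries deviated together from their group means. The pairing comes from this check and from the numbers in the labels, which name no shared day or culture. The correlations across genes for replicates 1, 2 and 3 were 0.31, 0.17 and 0.15 between 25 µM and 2i, 0.25, 0.11 and 0.14 between 50 µM and 2i, and 0.29, 0.13 and 0.16 between the doses. All exceeded 0.1, so values with the replicate number as a block are given for these 3 comparisons where they end or make a call or move a count of calls by over 1.5 times.

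Alternatives were DESeq2 size factors within edgeR, the Wald test of DESeq2 1.42.0, limma voom, no low-count filter, a filter of 1 CPM in 3 libraries, only the compared groups in the fit, the replicate block, a log2 fold minimum of 1, and each library left out in turn. List tests were repeated with an estimated correlation and with fry. The shift was repeated without holding a library out and without a fold minimum, and the index with a prior count of 0.5. A fit of replicates 2 and 3 only, and a test of the index with same-numbered libraries as pairs, were chosen after seeing the data.

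The methods were tested on simulated data, with 200 of 13230 genes changed. For 2i against primed, 25 µM against 2i, 50 µM against 2i and 50 against 25 µM, edgeR recovered 44, 38, 45 and 45% of genes changed by 1.5-fold and 77, 69, 75 and 74% of those changed by 2-fold. False calls were 6.2, 6.14, 6.98 and 4.8% of calls. In the simulated 50 µM comparison, camera called DNA replication factors shifted by 0.15 (adjusted p = 3.01e-13) and 0 of the other lists. Genes were drawn independently there, so this cannot show how camera behaves where genes of a list are correlated. In the real data the estimated correlation of that list was 0.074 at 50 µM against 2i. The shift measure gave 0.0027 with 0% of the response moved back and −0.373 with 25%.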

Results

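Mouse R1 embryonic stem cells, a male line, were profiled by 3′ mRNA sequencing before and after 6 days in 2i, a pair of inhibitors of MEK and GSK3 used to bring such cells to a naive state. The starting cells (day 0) grew in serum with LIF and are called primed in the labels. Here that name stands for the day 0 group and was not tested as a description of its state. 2i was given alone or together with an inhibitor of MRE11 at 25 or 50 µM. MRE11 is the nuclease of the MRE11-RAD50-NBN complex, which acts at DNA breaks and at replication forks. The title of the series asks, in other words, whether MRE11 and DNA replication take part in the passage from the primed to the naive state. Each of the 4 groups held 3 libraries, with 5894561 to 7060126 counts per library, and 13230 genes entered the tests. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Changes are log2 fold changes ± SE from edgeR, levels are library-scaled counts (CPM) as mean ± SD over n = 3 libraries, and gene positions are on GRCm38.

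The 4 groups separated on the first pair of principal components of the 1000 most variable genes. PC1 held 79.2% of the variance and set the primed libraries (mean score −59.7 ± 2.1, SD, n = 3) apart from 2i alone (17 ± 1.6), 25 µM (22.4 ± 1.1) and 50 µM (20.3 ± 1.1). PC2 held 9.44% and ordered the six-day groups by dose, from 16.3 ± 2.1 in 2i alone through 1 ± 3.8 at 25 µM to −16.8 ± 3.4 at 50 µM. Genes with at least 1 count numbered 19830 ± 180 in primed cells, 19570 ± 252 in 2i, 19170 ± 251 at 25 µM and 18800 ± 280 at 50 µM.

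**Figure D1:**
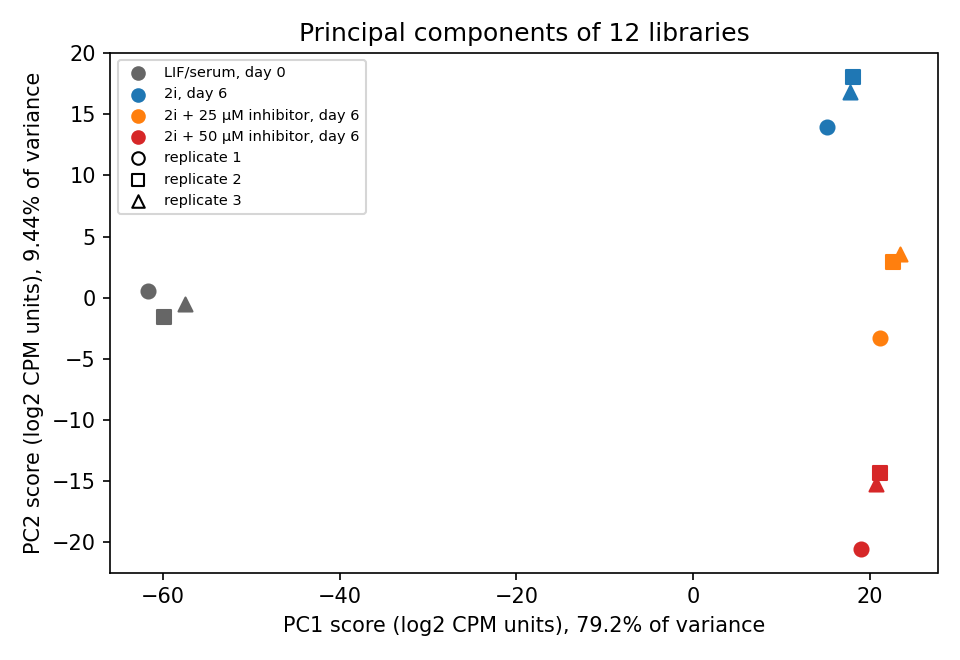
Scores of the 12 libraries on PC1 (79.2% of variance) and PC2 (9.44%), in log2 CPM units, with colour for the group and marker shape for the replicate number. Primed libraries lie at the left, around −59.7 on PC1, and the six-day groups run from 16.3 (2i alone) to −16.8 (50 µM) on PC2.

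The first comparison set cells after 6 days of 2i against primed cells at day 0. No group stayed in serum with LIF to day 6. Effects of 2i therefore cannot be told apart from those of time in culture or of any other change of medium. Changes in 2i, here and below, mean the difference between these groups. Naive pluripotency factors rose: Tfcp2l1, a transcription factor of the naive network (ENSMUSG00000026380, chromosome 1, 118627945 to 118685168), went from 84 ± 2.11 to 495 ± 17 CPM (n = 3 per group), a 5.89-fold rise with an edgeR adjusted p of 3.98e-15. Nanog, a core pluripotency factor (ENSMUSG00000012396, chromosome 6, 122707489 to 122714633), rose 2.15-fold from 550 ± 51.3 to 1180 ± 115 CPM (edgeR adjusted p = 5.98e-09). Tbx3 rose by 2.12 ± 0.13, Prdm14 by 1.60 ± 0.15, Klf4 by 1.14 ± 0.12, Esrrb by 0.62 ± 0.09 and Klf2 by 0.36 ± 0.09 on the log2 scale. Of 18 naive pluripotency factors measured, 12 rose, 3 fell and 3 were not called; adjusted over the list alone, 12 rose and 4 fell. The median log2 change of the list was 0.68 (camera adjusted p = 0.00032, and 0.024 with an estimated correlation). Zfp42 (0.03 ± 0.13) and Sox2 (−0.14 ± 0.09) were not called. Dppa3, an oocyte and germ cell factor that protects DNA methylation in the zygote (ENSMUSG00000046323, chromosome 6, 122626410 to 122630272), fell by 0.57 ± 0.21 with an edgeR adjusted p of 0.0459. That value became 0.133 without primed replicate 2, 0.114 without primed replicate 3, 0.158 without 2i replicate 1 and 0.105 without 2i replicate 3. Pou5f1, whose reads may be shared with pseudogenes, carried few counts, and its level is uncertain.

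Markers of the primed and formative epiblast fell together. Of 21 measured, none rose, 18 fell and 3 were not called, with the same counts adjusted over the list alone (median −2.66; camera adjusted p = 1e-15, and 0.0058 with an estimated correlation). Otx2, a transcription factor of the formative epiblast (ENSMUSG00000021848, chromosome 14, 48657677 to 48673819), fell from 248 ± 32.6 to 41.2 ± 2.93 CPM, a log2 change of −2.58 ± 0.11. Pou3f1 changed by −4.09 ± 0.22, Sox4 by −2.78 ± 0.15 and Tcf15 by −2.67 ± 0.13. Fgf5, a growth factor of the primed epiblast, had 3.16 ± 1.14 CPM in primed cells and no counts in 2i. That is 20.4-fold lower at a floor of 3 counts over the group. Of 16 general pluripotency factors 1 rose, 8 fell and 7 were not called, and adjusted over the list alone 3 rose and 8 fell (median −0.38, camera adjusted p = 0.0041; adjusted p = 0.2 with an estimated correlation). Among them Lin28a, an RNA-binding repressor of let-7, changed by −3.01 ± 0.12 and Utf1 by −2.33 ± 0.16.

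**Figure D2:**
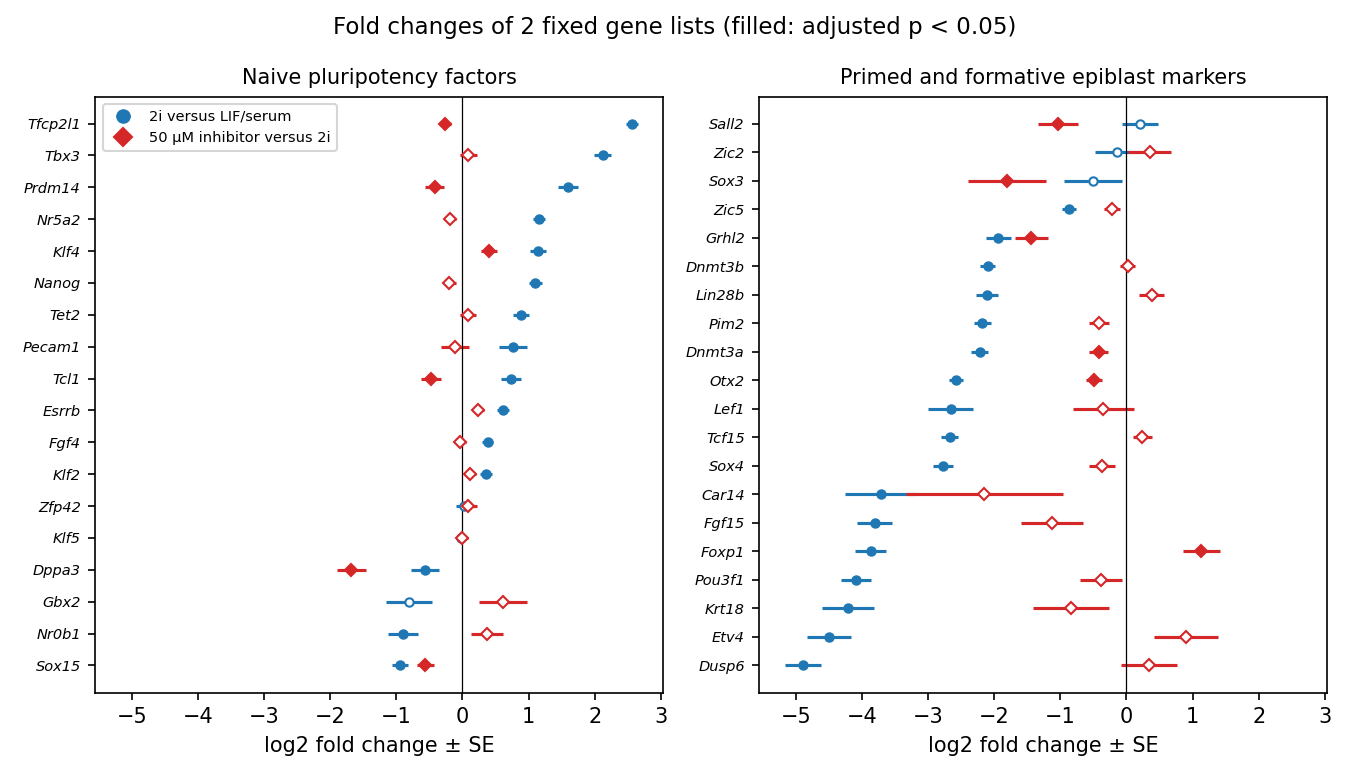
Log2 fold changes ± SE of the naive pluripotency factors (left) and the primed and formative epiblast markers (right), with blue circles for 2i against primed cells and red diamonds for 50 µM inhibitor against 2i alone; filled symbols have an edgeR adjusted p below 0.05, and Fgf5 is left out because it had no counts in 2i. The primed and formative markers have a median of −2.66 in 2i, and the red diamonds of the naive factors have a median of −0.02.

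Transcripts induced by ERK signalling, the pathway that MEK inhibition blocks, fell in 2i. Of 21 ERK pathway targets 1 rose, 18 fell and 2 were not called; adjusted over the list alone, 1 rose and 19 fell (median −1.34; camera adjusted p = 9e-09, and 0.019 with an estimated correlation). Dusp6, a phosphatase that acts on ERK (ENSMUSG00000019960, chromosome 10, 99263231 to 99267489), fell 29.6-fold from 59.7 ± 16.1 to 1.99 ± 0.463 CPM. Spry4, a feedback inhibitor of the pathway, changed by −6.77 ± 0.36 and the immediate-early factor Egr1 by −5.31 ± 0.27. Wnt/beta-catenin targets, which GSK3 inhibition can raise, went both ways: of 13 measured 6 rose, 4 fell and 3 were not called, the same adjusted over the list alone, and the list was not called (camera adjusted p = 0.25). Axin2 (1.74 ± 0.16) and Apcdd1 (2.67 ± 0.20), both feedback inhibitors of Wnt signalling, were among those that rose. Of 14 LIF/STAT3 targets 4 rose, 6 fell and 4 were not called (4 and 7 adjusted over the list alone; camera adjusted p = 0.66).

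The de novo DNA methyltransferases Dnmt3a and Dnmt3b and their partner Dnmt3l fell by 2.22 ± 0.13, 2.10 ± 0.11 and 2.13 ± 0.12 on the log2 scale. In the list of DNA methylation machinery as a whole, 2 of 15 members rose, 5 fell and 8 were not called, the same adjusted over the list alone (camera adjusted p = 0.25). Of 25 methylation-sensitive germline genes, which promoter methylation silences in somatic cells, 9 rose, 12 fell and 4 were not called, again the same adjusted over the list alone (median −0.37, camera adjusted p = 0.52); Rpl10l rose by 1.68 ± 0.12, with reads that may be shared with Rpl10, and Mael changed by −2.33 ± 0.18. Of 29 imprinted genes 3 rose, 15 fell and 11 were not called, and adjusted over the list alone 4 rose and 16 fell (median −0.78, camera adjusted p = 0.00032; adjusted p = 0.2 with an estimated correlation). Nnat changed by −4.48 ± 0.25, Phlda2 by −3.39 ± 0.20 and Peg10 by −2.97 ± 0.15. None of the 9 genes of the 2-cell-like state, an early-embryo program seen in rare stem cells, was called over all genes or adjusted over the list alone (median 0.68, camera adjusted p = 0.42). Of these 9 by edgeR, 1 was higher at an unadjusted p under 0.05, and none was called by DESeq2 or limma voom.

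Metabolic and stress lists also moved. Of 26 integrated stress response targets 3 rose, 18 fell and 5 were not called; adjusted over the list alone, 3 rose and 20 fell (median −0.77, camera adjusted p = 2.4e-05; adjusted p = 0.2 with an estimated correlation). Asparagine synthetase Asns (1.19 ± 0.09) and Cth (0.89 ± 0.11), an enzyme of cysteine synthesis, rose, while the amino acid transporter Slc7a3 changed by −1.06 ± 0.10 and the serine synthesis enzyme Psat1 by −0.85 ± 0.10. Of 26 genes of glycolysis and lactate handling 3 rose, 15 fell and 8 were not called, the same adjusted over the list alone (median −0.49, camera adjusted p = 0.00046; adjusted p = 0.24 with an estimated correlation). Pdk1, a kinase that inhibits pyruvate dehydrogenase, changed by −2.87 ± 0.13, the lactate exporter Slc16a3 by −2.27 ± 0.20 and hexokinase Hk1 by 0.99 ± 0.12. Of 32 ribosome biogenesis factors none rose, 13 fell and 19 were not called, with 14 falls adjusted over the list alone (median −0.25, camera adjusted p = 0.00079; adjusted p = 0.42 with an estimated correlation); Heatr1 changed by −0.60 ± 0.08 and Rrp9 by −0.55 ± 0.11, and 8 members fell without 2i replicate 2.

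The other lists were not called in 2i against primed cells, with camera adjusted p between 0.054 and 0.96. Among 61 factors of the MRE11 complex, fork protection and double-strand break repair, 7 rose, 7 fell and 47 were not called (6 and 6 adjusted over the list alone). Mre11a (ENSMUSG00000031928, chromosome 9, 14784654 to 14837123) changed by −0.39 ± 0.10 and Rad50 by −0.53 ± 0.09, whereas Nbn, at −0.02 ± 0.13, was not called. Fancm, a helicase of stalled forks, rose by 1.11 ± 0.11. Of 61 DNA replication factors 11 rose, 6 fell and 44 were not called, also adjusted over the list alone; cyclin Ccne1 changed by −0.83 ± 0.09 and the fork factor Donson by 0.83 ± 0.14. Of 30 p53 targets 11 rose and 3 fell, also adjusted over the list alone, among them the cell cycle inhibitor Cdkn1a (2.00 ± 0.13) and Mdm2 (0.42 ± 0.09). Of 30 genes of G2/M and mitosis none rose and 5 fell, with none in either direction adjusted over the list alone, and the 5 became 0 without primed replicate 2, 3 without primed replicate 3 and 1 without 2i replicate 3. Among 26 Polycomb complex subunits 12 rose and 4 fell (12 and 5 adjusted over the list alone), among them Bmi1 (1.95 ± 0.18) and Phf19 (−3.72 ± 0.33). Of 19 interferon-stimulated genes 6 rose and 9 fell, the same adjusted over the list alone. The immunoproteasome subunit Psmb8 had 9.18 ± 1.68 CPM in primed cells and no counts in 2i, 59.3-fold lower at a floor of 3 counts over the group.

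Markers of other cell types went both ways in 2i, as did the remaining stress and metabolic lists except the mitochondrially encoded genes; counts in parentheses are those adjusted over the list alone. Of 8 mesoderm and primitive streak markers 5 rose and 1 fell (5 and 2), with Gsc at 3.42 ± 0.37 and Bmp4 at −2.53 ± 0.21. Of 11 primitive and definitive endoderm markers 4 rose and 3 fell (4 and 4), of 9 neuroectoderm markers 1 rose and 5 fell (1 and 6), and of 12 trophoblast markers 2 rose and 6 fell (2 and 6). Of 11 fibroblast and feeder-cell markers 1 rose, Fn1 at 1.04 ± 0.09, and 7 fell (1 and 7), among them Timp3 at −2.68 ± 0.29. Of 20 endoplasmic reticulum chaperones 4 rose and 2 fell (4 and 2), of 5 aryl hydrocarbon receptor targets 2 rose and 1 fell (2 and 1), and of 54 oxidative phosphorylation subunits 5 rose and 2 fell (5 and 2). Of 20 NRF2 antioxidant targets 4 rose and 6 fell (4 and 7), and the median (−0.05) and the mean (0.14) of that list differ in sign. Of 24 genes of cholesterol biosynthesis and uptake 5 rose and 4 fell (4 and 4), with median and mean both 0 to 2 decimals. Of 8 mitochondrially encoded genes none rose and 1, mt-Nd6 (−0.50 ± 0.13), fell (0 and 1), and that list's median (0.01) and mean (−0.04) differ in sign too. Without primed replicate 2, 4 NRF2 targets rose and 2 fell, and 3 cholesterol genes rose and 2 fell; the cholesterol counts were 2 and 2 without primed replicate 3, 1 and 1 without 2i replicate 1 and 2 and 3 without 2i replicate 2. Without primed replicate 3, 2 endoderm markers rose and 2 fell.

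In all, 5346 of the 13230 genes tested (40.4%) differed between 2i and primed cells, 2651 higher and 2695 lower in 2i, and 949 and 1179 of these by 2-fold or more. Among genes that passed the rule for naming, with a mean log2 CPM of at least 3, the largest rises were those of Ly6a, a surface antigen (12.5 ± 1.65 to 274 ± 33.4 CPM, 21.9-fold), the innate immune factor Pglyrp1 (4.25 ± 0.28), the imprinted zinc finger factor Plagl1 (4.24 ± 0.23) and the homeobox factor Meis2 (4.18 ± 0.16). The falls of Id1, a target of BMP signalling (92.5 ± 30.3 to 3.03 ± 0.548 CPM), Enox1 (−4.58 ± 0.41), keratin Krt18 (−4.21 ± 0.39) and the calcium-binding protein S100a6 (−4.05 ± 0.20) were among the largest under the same rule, while genes of lower mean level, such as Spry4, fell further. With the 6 libraries split in other ways, camera called up to 9 lists, against 8 in the real split.

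The comparison of 25 µM MRE11 inhibitor in 2i with 2i alone called 124 genes, or 627 with the replicate number as a block. Of the lists, germline and 2-cell-like genes had the lowest camera adjusted p. Rhox5, a homeobox gene of the reproductive tract and a common readout of promoter methylation (ENSMUSG00000095180, chromosome X, 37804842 to 37808876), fell from 431 ± 41.3 to 225 ± 38.9 CPM (n = 3 per group; edgeR adjusted p = 0.00149). The laminin chain Lamb1 fell from 28.3 ± 6.01 to 14.2 ± 1.04 CPM. Ribosomal protein gene Rpl13a (ENSMUSG00000074129, chromosome 7, 45125558 to 45128761) rose from 369 ± 12.5 to 717 ± 27.2 CPM (edgeR adjusted p = 2.82e-06), though it has processed copies with which reads may be shared. The histone genes Hist1h2ae (1.22 ± 0.19) and Hist1h4i (1.11 ± 0.19) rose too, likewise uncertain because histone genes are near-identical copies.

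At 25 µM, 3 of the 25 methylation-sensitive germline genes fell, none rose and 22 were not called; adjusted over the list alone 16 fell, and with the replicate number as a block 11 fell over all genes. The median of the list was −0.72 (camera adjusted p = 3.3e-15, and 0.0029 with an estimated correlation). The testis bromodomain gene Brdt changed by −2.36 ± 0.40 (edgeR adjusted p = 0.00639, and 0.0584 without 2i replicate 3, when 1 member of the list fell over all genes). Of the 9 genes of the 2-cell-like state 5 fell, none rose and 4 were not called, while adjusted over the list alone all 9 fell, and 8 fell with the replicate block (median −2.27; camera adjusted p = 4e-12, and 0.0027 with an estimated correlation). Their summed level was 18.9, 22.2 and 25 CPM in the 3 libraries of 2i and 3.92, 5.21 and 4.4 CPM at 25 µM. The Zscan4 and Usp17l families on this list are near-identical copies, so single members are uncertain. The 5 calls became 3, 1 and 0 without 2i replicates 1, 2 and 3, and 1, 2 and 1 without 25 µM replicates 1, 2 and 3.

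DNA replication factors moved upward at 25 µM: of 61, 5 rose, none fell and 56 were not called, with 7 rises and 1 fall adjusted over the list alone and 11 rises and 1 fall with the replicate block. The median was 0.11 (camera adjusted p = 1.2e-05; adjusted p = 0.24 with an estimated correlation). The origin licensing factor Cdt1 rose by 0.50 ± 0.08 (edgeR adjusted p = 0.00639, and 0.0584 without 2i replicate 3). The 5 rises of the list became 3, 3 and 0 without 2i replicates 1, 2 and 3, and 1, 2 and 1 without 25 µM replicates 1, 2 and 3. None of 54 oxidative phosphorylation subunits was called by edgeR, or adjusted over the list alone (7 were higher at an unadjusted p under 0.05; DESeq2 and limma voom called none). Of the subunits 1 rose with the replicate block, yet the list as a whole was called upward (median 0.10, camera adjusted p = 0.00018; adjusted p = 0.47 with an estimated correlation). None of 26 integrated stress response targets was called by edgeR over all genes (1 higher and 6 lower at an unadjusted p under 0.05, 1 lower by DESeq2, none by limma voom). Adjusted over the list alone 1 rose and 5 fell, 1 fell over all genes without 25 µM replicate 3, and 1 rose and 4 fell with the replicate block. The median was −0.28 (camera adjusted p = 0.00021; adjusted p = 0.33 with an estimated correlation).

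Fibroblast, endoderm and trophoblast markers were called lower as lists at 25 µM, and each call was weak. Neuroectoderm (median 0.08, camera adjusted p = 0.19) and mesoderm markers (median 0.06, camera adjusted p = 0.2) were not called as lists. Of 11 fibroblast and feeder-cell markers 1 fell, 10 were not called, and 3 fell adjusted over the list alone (median −1.02, camera adjusted p = 0.017; adjusted p = 0.24 with an estimated correlation). That call ended without 2i replicate 1 (0.062), 2i replicate 2 (0.058), 25 µM replicate 1 (0.1) or 25 µM replicate 3 (0.079), while the replicate block gave 5 falls. The member that fell, collagen gene Col1a1 (−1.99 ± 0.44, edgeR adjusted p = 0.0443), was not called by limma voom (0.201). Leaving out 2i replicates 1, 2 and 3 gave an edgeR adjusted p of 0.118, 0.147 and 0.0858, and 25 µM replicates 1, 2 and 3 gave 0.136, 0.162 and 0.173. The list then had 0 members called, or 1 without 2i replicate 3. Of 11 endoderm markers only Lamb1 fell, also adjusted over the list alone, and 3 fell with the replicate block (median −0.34, camera adjusted p = 0.016, and 0.074 without 2i replicate 1; adjusted p = 0.45 with an estimated correlation). None of 12 trophoblast markers was called by edgeR over all genes or adjusted over the list alone (2 lower at an unadjusted p under 0.05; none by DESeq2 or limma voom), and 2 fell with the replicate block. The median was −0.26 (camera adjusted p = 0.026, and 0.056 in replicates 2 and 3 only, a setting chosen after seeing the data; adjusted p = 0.31 with an estimated correlation). With the replicate block the camera test also called DNA methylation machinery upward (adjusted p = 0.047, against 0.095) and cholesterol genes downward (0.033, against 0.067); without the block, neither was called with an estimated correlation (adjusted p = 0.47 for each).

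The naive and primed identities were not called at 25 µM. None of the 18 naive factors and none of the 21 primed and formative markers was called by edgeR, either over all genes or adjusted over the list alone (medians −0.02 and −0.20; camera adjusted p = 0.46 and 0.17). The replicate block called 1 naive factor lower and 1 primed marker in each direction. At an unadjusted edgeR p under 0.05, 3 naive factors were lower, and 1 primed marker was higher and 2 were lower; DESeq2 and limma voom called none. Nanog (−0.08 ± 0.10), Tfcp2l1 (−0.16 ± 0.08) and Otx2 were not called with or without the block. Dppa3 (−0.50 ± 0.21) had an edgeR adjusted p of 0.342, and 0.000407 with the replicate block. Axin2 (−0.60 ± 0.15) had 0.0538 and, with the block, 0.00372, both edgeR adjusted p. Of the MRE11 complex, Mre11a (0.11 ± 0.10) and Nbn (−0.05) were not called, and Rad50 (−0.36 ± 0.09) had an edgeR adjusted p of 0.0693, or 0.00112 with the block. Of the 61 factors of that complex, fork protection and break repair 1 rose, none fell and 60 were not called, with 1 rise and 2 falls adjusted over the list alone and 3 rises and 2 falls with the block (camera adjusted p = 0.19). Of 30 p53 targets 1 rose and 29 were not called, with 2 rises and 1 fall adjusted over the list alone and also 2 and 1 with the block (camera adjusted p = 0.2). The rise in the repair list and that in the p53 list were each lost without 2i replicates 1, 2 or 3 or 25 µM replicates 1 or 2, which left 0.

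In all, 124 genes differed at 25 µM, 60 higher and 64 lower than in 2i, and with the replicate number as a block 627 did, 328 higher and 299 lower. Without 2i replicate 1, 39 were higher and 62 lower. The count fell to 38 without 2i replicate 2, 29 without 2i replicate 3, and 48, 33 and 39 without 25 µM replicates 1, 2 and 3. In other splits of the 6 libraries camera called up to 8 lists, as many as in the real split.

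At 50 µM 1994 genes, among them Dppa3 and Rhox5, differed from 2i alone, against 124 at 25 µM. Dppa3 fell 3.2-fold, from 124 ± 22.8 to 38.5 ± 12.1 CPM (n = 3 per group; edgeR adjusted p = 0.000582). Rhox5 fell from 431 ± 41.3 to 142 ± 21 CPM (edgeR adjusted p = 2.16e-07). Bmp4, a growth factor of the TGF-beta family (ENSMUSG00000021835, chromosome 14, 46383520 to 46390669), rose 4.05-fold from 42.5 ± 7.5 to 172 ± 40.1 CPM (edgeR adjusted p = 6.42e-05). Rpl13a rose to 977 ± 90.5 CPM, and Dab1, an adaptor of reelin signalling (ENSMUSG00000028519, chromosome 4, 103619359 to 104744844), from 3.39 ± 0.542 to 14.9 ± 2.73 CPM.

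Of the 25 germline genes 1 rose, 14 fell and 10 were not called, and adjusted over the list alone 1 rose and 16 fell (median −0.98; camera adjusted p = 8.5e-10, and 0.013 with an estimated correlation). Tex19.1, a germ cell gene that also acts in placenta, fell from 423 ± 74.8 to 186 ± 20.5 CPM, Fkbp6 changed by −1.18 ± 0.16 and Brdt by −3.17 ± 0.45. Of the 14 that fell, 10 were also below their primed level at 50 µM and 2 were above it. All 9 measured genes of the 2-cell-like state (of 21 listed) fell, also adjusted over the list alone. The fitted median of −4.86 becomes −3.83 with 2 members at 0 counts set to the floor of 3 counts (camera adjusted p = 9.6e-10, and 0.0057 with an estimated correlation). Each of the 9 had 35 to 75 counts over the 2i libraries and 0 to 6 at 50 µM. They thus passed the low-count filter only through 2i or primed libraries, which favours genes high in those groups. The unmeasured members are not covered. Zscan4d (ENSMUSG00000090714, chromosome 7, 11161374 to 11166159) had 42 counts over the 3 libraries of 2i and none at 50 µM. That is 13.4-fold lower at the floor of 3 counts over the group. The exact 95% counting interval of the ratio begins at 10.4. Tmem92 had 55 counts in 2i and 1 at 50 µM, a ratio of 52.3 with a 95% counting interval of 9.01 to 2100, and Sp110 had 75 and 2 (35.7, 9.54 to 300). The summed level of the list was 0.705, 0.895 and 1.13 CPM at 50 µM and 18.6, 13.3 and 16.5 CPM in primed cells.

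**Figure D3:**
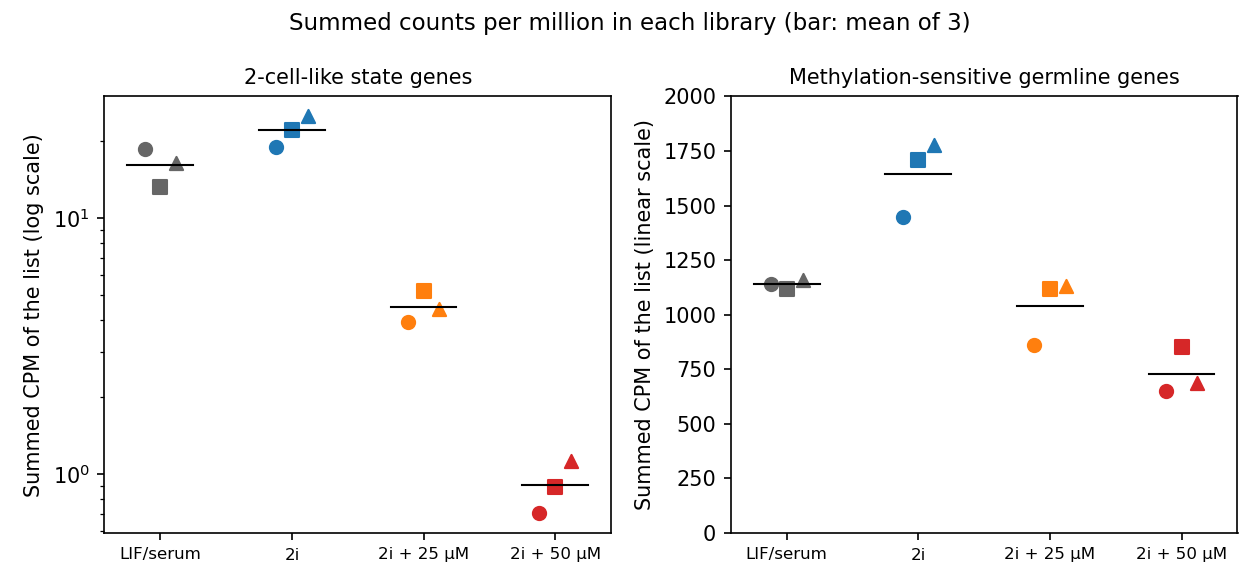
Summed CPM of the 9 measured 2-cell-like state genes (left, log scale) and the 25 methylation-sensitive germline genes (right, linear scale) in each library, with marker shape for the replicate number and a bar at the mean of 3. The 2-cell-like sum lies at 18.9 to 25 CPM in 2i and 0.705 to 1.13 CPM at 50 µM, and the germline sum at 1450 to 1780 CPM in 2i and 650 to 852 CPM at 50 µM. Rhox5, Tex19.1 and Rpl10l, the last with reads that may be shared with Rpl10, carry most of the germline sum in 2i. The right panel therefore mainly follows these genes.

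DNA replication factors were higher at 50 µM: of 61, 15 rose, 2 fell and 44 were not called, with 17 and 3 adjusted over the list alone and 26 and 4 with the replicate block. The median was 0.18 (camera adjusted p = 9.9e-06; adjusted p = 0.17 with an estimated correlation). The GINS helicase subunit Gins2 rose by 0.72 ± 0.09, Cdt1 by 0.71 ± 0.08 and the fork protection factor Timeless by 0.60 ± 0.10, and Ccne1 changed by −0.52 ± 0.09; without 50 µM replicate 1, 9 members rose and 2 fell. Among the 61 factors of the MRE11 complex, fork protection and break repair 8 rose, 4 fell and 49 were not called (10 and 5 adjusted over the list alone; 3 and 4 by DESeq2), and the list was not called (camera adjusted p = 0.079). Its counts were 3 and 3 without 2i replicate 1 or 50 µM replicate 1, and 4 and 3 without 50 µM replicate 3. Histone variant gene H2afx rose by 0.78 ± 0.12, Trp53bp1, a break repair mediator, changed by −0.53 ± 0.11 and Rad50 by −0.37 ± 0.09, while Mre11a (0.14 ± 0.10) and Nbn (0.08 ± 0.13) were not called. Of 15 genes of the DNA methylation machinery 3 rose, 1 fell and 11 were not called, with 4 and 1 adjusted over the list alone and 5 and 1 with the block (median 0.13, camera adjusted p = 0.022; adjusted p = 0.37 with an estimated correlation). That call ended without 2i replicate 2 (0.095), 50 µM replicate 1 (0.063) or 50 µM replicate 2 (0.081), and 2 members rose and none fell without 2i replicate 2 or 50 µM replicates 1 or 3. Uhrf1, a cofactor of maintenance methylation, rose from 134 ± 6.62 to 205 ± 20.9 CPM, and Dnmt3b (0.02 ± 0.11) and Dnmt3l (−0.06 ± 0.13) were not called. Of 30 p53 targets 3 rose and 5 fell (3 and 6 adjusted over the list alone; camera adjusted p = 0.57), with a median of 0.02 and a mean of −0.06. The counts were 2 and 1 without 2i replicate 2, 3 and 2 without 2i replicate 3, 1 and 2 without 50 µM replicate 1 and 2 and 2 without 50 µM replicate 3. Cdkn1a (0.05) and Mdm2 (−0.14) were not called.

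Integrated stress response targets fell: 11 of 26, with 1 rise and 14 not called, and 1 rise and 12 falls adjusted over the list alone (median −0.60, camera adjusted p = 7.5e-06; adjusted p = 0.17 with an estimated correlation). Cth changed by −1.31 ± 0.12, Ddit4, an inhibitor of mTORC1, by −1.22 ± 0.12 and Slc7a3 by 0.57 ± 0.10. Of 54 oxidative phosphorylation subunits 9 rose and none fell, the same adjusted over the list alone, and 19 rose with the replicate block. The median was 0.15 (camera adjusted p = 9.9e-06; adjusted p = 0.37 with an estimated correlation), and the complex I subunit Ndufb10 rose by 0.43 ± 0.09. The 9 rises became 4 without 2i replicate 2 or 3, 5 without 50 µM replicate 1 and 2 without 50 µM replicate 3. Of 8 mitochondrially encoded genes 2 rose, also adjusted over the list alone, and 5 with the block, with mt-Cytb at 0.57 ± 0.10. The median was 0.24 (camera adjusted p = 0.013, and 0.065 without 50 µM replicate 1; adjusted p = 0.37 with an estimated correlation), and 1 rose without 2i replicate 2, 2i replicate 3 or 50 µM replicate 1. The share of counts on all mitochondrially encoded genes, with their ribosomal RNAs, covers more than the 8 genes of the list. That share was 5.887 ± 0.808% at 50 µM, 5.117 ± 0.543% at 25 µM, 4.94 ± 0.382% in 2i and 4.847 ± 0.399% in primed cells. An exact two-sided permutation test of 50 µM against 2i gave p = 0.1 for that share, the smallest that 3 against 3 libraries allow. In replicates 1, 2 and 3 the share was 6.82, 5.42 and 5.42% at 50 µM and 5.38, 4.75 and 4.69% in 2i. At 25 µM it was 5.69, 5.05 and 4.61%. Each same-numbered pair was thus higher at 50 µM than in 2i or at 25 µM, and replicate 1 was the highest at 50 µM.

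Trophoblast, fibroblast and endoderm markers were called lower as lists at 50 µM, beside the fall in genes detected. Of 12 trophoblast markers none rose and 6 fell, with 7 falls adjusted over the list alone (median −0.86, camera adjusted p = 0.00011; adjusted p = 0.083 with an estimated correlation). Among them were Peg10 (−1.15 ± 0.18) and the transcription factor Tfap2a (20 ± 2.94 to 9.96 ± 2.37 CPM). The 6 falls became 2 without 2i replicate 2, 3 without 2i replicate 3 and 2 without 50 µM replicate 3. Of 11 fibroblast and feeder-cell markers 5 fell, also adjusted over the list alone, and none rose (median −1.49, camera adjusted p = 0.0091; adjusted p = 0.17 with an estimated correlation). Without 50 µM replicate 1 or 2 the camera value was 0.052, and 3 fell without 50 µM replicate 1, 2 or 3. The surface antigen Thy1 changed by −4.05 ± 0.43 and collagen Col1a1 by −3.21 ± 0.52. Of 11 endoderm markers 1 rose and 3 fell, with 1 and 6 adjusted over the list alone and 1 and 5 with the replicate block (median −0.58, camera adjusted p = 0.014; adjusted p = 0.37 with an estimated correlation). Lamb1 was at −1.64 ± 0.16, and none rose and 2 fell without 2i replicate 3. Neuroectoderm markers went the other way: 3 of 9 rose and none fell, the same adjusted over the list alone (median 0.61, camera adjusted p = 0.0091; adjusted p = 0.18 with an estimated correlation), with Stmn2 at 0.88 ± 0.10 and Ncam1 at 0.75 ± 0.10. Of 13 Wnt targets 2 rose and 5 fell, the same adjusted over the list alone (median −0.42, camera adjusted p = 0.049; adjusted p = 0.37 with an estimated correlation). That call ended with the replicate block (0.058) and without 2i replicate 2 (0.052), 2i replicate 3 (0.051) or 50 µM replicate 1 (0.063). The Wnt-responsive factor Sp5 changed by −2.60 ± 0.38, Apcdd1 by −1.11 ± 0.17 and Axin2 by −0.74 ± 0.15.

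Neither pluripotency list was called at 50 µM. Of the 18 naive factors 1 rose, 5 fell and 12 were not called (2 and 5 adjusted over the list alone, 3 and 7 with the replicate block; median −0.02, camera adjusted p = 0.3). Of the 21 primed and formative markers 1 rose, 5 fell and 15 were not called (1 and 6 adjusted over the list alone; median −0.37, camera adjusted p = 0.09). The naive counts were 0 and 2 without 2i replicate 2, and 0 and 3 without 2i replicate 3, 50 µM replicate 1 or 50 µM replicate 3. The primed counts were 0 and 2 without 2i replicate 2, 1 and 2 without 2i replicate 3, 0 and 2 without 50 µM replicate 1 and 0 and 3 without 50 µM replicate 3. Otx2 changed by −0.49 ± 0.12 and the epithelial factor Grhl2 by −1.44 ± 0.25. Nanog (−0.20 ± 0.10) had an edgeR adjusted p of 0.171 and Esrrb (0.24 ± 0.09) one of 0.0772; with the replicate block these were 0.0366 and 0.0148. Klf4 rose by 0.40 ± 0.12 (edgeR adjusted p = 0.0264). That call ended without 2i replicate 2 (0.0944), 2i replicate 3 (0.0978), 50 µM replicate 1 (0.18) or 50 µM replicate 3 (0.0679). Among the 5 naive factors that fell were Dppa3 (−1.68 ± 0.22) and Sox15 (−0.56 ± 0.13). Prdm14 (−0.42 ± 0.14) and Tfcp2l1 (−0.26 ± 0.08) fell too, with edgeR adjusted p of 0.0481 and 0.0293. By the counts above, some of the 5 falls lost their call without 1 library.

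In all, 1994 genes differed at 50 µM from 2i alone (15.1% of those tested), 927 higher and 1067 lower, and 150 and 469 of them by 2-fold or more. Under the replicate block 3240 differed, 1599 higher and 1641 lower. The count was 1217 without 2i replicate 2 and 1284 without 2i replicate 3. The higher genes alone numbered 594, 505 and 560 without 2i replicates 1, 2 and 3 and 552 and 536 without 50 µM replicates 1 and 3, against 1074, 712, 724, 816 and 896 lower.

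Between the doses, the genes that differed were mostly lower at 50 than at 25 µM. The phosphatase subunit gene Ppp2r2c fell from 90 ± 7.44 to 38.1 ± 6.37 CPM (n = 3 per group; edgeR adjusted p = 6.93e-06). The collagen receptor Ddr2 changed by −1.24 ± 0.13, Thy1 by −3.03 ± 0.49, Cth by −0.90 ± 0.12 and Ddit4 by −0.79 ± 0.12. Dab1 rose by 1.05 ± 0.19 and Stmn2, a neuronal microtubule regulator, by 0.69 ± 0.10. Dppa3 fell by 1.18 ± 0.23 (edgeR adjusted p = 0.034), which became 0.129 without 25 µM replicate 2, 0.152 without 25 µM replicate 3 and 0.0678 without 50 µM replicate 2. In all, 153 genes differed, 24 higher and 129 lower at 50 µM. With the replicate block 542 genes differed, 168 higher and 374 lower, and 238 in replicates 2 and 3 only, a setting chosen after seeing the data. The count was 38 without 25 µM replicate 2, 42 without 25 µM replicate 3, 68 without 50 µM replicate 1 and 73 without 50 µM replicate 3. Without 25 µM replicate 1, 46 were higher and 157 lower, and without 50 µM replicate 2, 27 and 80.

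Of the 10 lists called between the doses, none was called with an estimated correlation. The 2-cell-like genes had no member called by edgeR over all genes, DESeq2 or limma voom, 5 lower at an unadjusted edgeR p under 0.05 and 1 fall adjusted over the list alone. The median was −2.70 (−1.91 at the floor; camera adjusted p = 0.0011; adjusted p = 0.08 with an estimated correlation). Of 26 integrated stress response targets 3 fell, also adjusted over the list alone (camera adjusted p = 0.0015; adjusted p = 0.34 with an estimated correlation). Of 12 trophoblast markers 1 fell, and 4 adjusted over the list alone (0.0017; adjusted p = 0.21 with an estimated correlation), and of 9 neuroectoderm markers 1 rose, and 3 adjusted over the list alone (0.0064; adjusted p = 0.25 with an estimated correlation). The other called lists each lost the call without at least 1 library. Germline genes (2 of 25 fell, also adjusted over the list alone; camera adjusted p = 0.029; adjusted p = 0.34 with an estimated correlation) lost it without 25 µM replicates 2 (0.097) or 3 (0.085) or 50 µM replicates 1 (0.11) or 3 (0.12). DNA replication factors (1 of 61 fell, also adjusted over the list alone, with the list upward; 0.034; adjusted p = 0.56 with an estimated correlation) lost it without 25 µM replicates 2 (0.17) or 3 (0.085) or 50 µM replicate 1 (0.45). The p53 targets (1 of 30 fell, also adjusted over the list alone; 0.021; adjusted p = 0.23 with an estimated correlation) lost it without 25 µM replicate 1 (0.057) or 50 µM replicate 3 (0.056). Glycolysis genes, oxidative phosphorylation subunits and mitochondrially encoded genes had no member called over all genes, and 1 mitochondrial gene rose adjusted over the list alone. At an unadjusted edgeR p under 0.05, 7 glycolysis genes were lower, and 2 oxidative phosphorylation subunits and 3 mitochondrial genes higher; DESeq2 called 1 glycolysis gene lower, 1 mitochondrial gene higher and no subunit, and limma voom none. Their camera adjusted p were 0.027, 0.015 and 0.0064 (adjusted p = 0.56, 0.65 and 0.35 with an estimated correlation). Glycolysis genes lost the call without 25 µM replicates 2 (0.053) or 3 (0.074) or 50 µM replicate 1 (0.25). Oxidative phosphorylation lost it without 25 µM replicate 1 (0.11) or 50 µM replicate 3 (0.91), and mitochondrial genes without 25 µM replicate 3 (0.085) or 50 µM replicate 1 (0.11). The called members of the trophoblast, germline and replication lists fell to 0 without 25 µM replicates 2 or 3 or 50 µM replicates 1 or 3. In these 10 lists the block gave, adjusted over all genes, 1 fall of 2-cell-like genes, 3 of trophoblast markers, 4 of germline genes, 3 of p53 targets and 5 of glycolysis genes, 2 rises of neuroectoderm markers, 1 of oxidative phosphorylation subunits, 2 of mitochondrial genes and 1 of stress response targets (their 3 falls stayed at 3), and 1 replication factor in each direction. With the replicate block DNA methylation machinery (0.039) and fibroblast markers (0.047) were called as well, but without the block neither was called with an estimated correlation (adjusted p = 0.6 and 0.34).

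All 124 genes called at 25 µM had the same sign at 50 µM, and 111 of them a larger change. The median size of their log2 change was 0.732 at 25 µM and 1.06 at 50 µM. Both doses shared 60 of the 60 genes higher at 25 µM and 63 of the 64 lower, against 4.2 and 5.16 for independent lists and means of 0.05 and 0 in 20 simulations of unchanged groups against the same controls, which leave out the effects and do not measure what the shared controls add. Part of the excess may come from the shared 2i libraries. With the replicate block the doses shared 299 higher and 269 lower genes (39.6 and 37.1 for independent lists). The shared count of 123 was 37 without 2i replicate 2, 29 without 2i replicate 3, and 48, 32 and 37 without 25 µM replicates 1, 2 and 3.

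**Figure D4:**
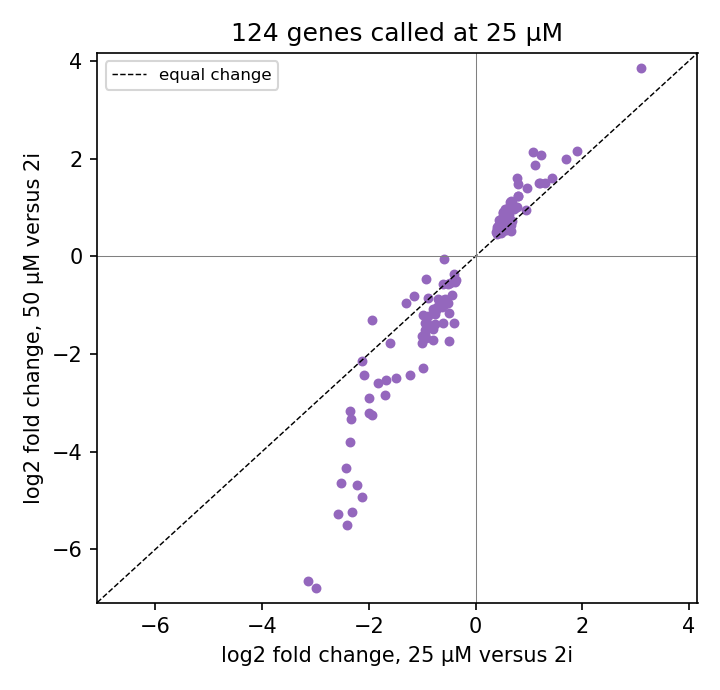
Log2 fold change against 2i alone at 25 µM (horizontal) and 50 µM (vertical) of the 124 genes called at 25 µM, with a dashed line at equal change. All 124 points have the same sign on both axes, and 111 lie farther from 0 at 50 µM.

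Against primed cells, both inhibitor groups kept the direction of 2i in the main pluripotency genes. Tfcp2l1 rose by 2.39 ± 0.09 at 25 µM and 2.29 ± 0.09 at 50 µM, and Nanog by 0.91 ± 0.10 at 50 µM. Otx2 changed by −3.08 ± 0.12 at 50 µM. Fgf5 had no counts at either dose and was 20.5-fold lower at 25 µM and 19.4-fold lower at 50 µM at the floor of 3 counts. Dppa3 was below its primed level of 183 ± 25.3 CPM, by −1.07 ± 0.21 at 25 µM and −2.25 ± 0.22 at 50 µM (n = 3 per group). Rad50 changed by −0.90 ± 0.09 at 50 µM. In all, 5594 genes differed from primed cells at 25 µM (2822 higher, 2772 lower) and 5859 at 50 µM (2985 higher, 2874 lower).

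The difference between the mean log2 CPM of the naive list and that of the primed and formative list was 1.78 ± 0.16 in primed cells, 4.85 ± 0.08 in 2i, 4.97 ± 0.11 at 25 µM and 5.02 ± 0.06 at 50 µM (SD, n = 3). Exact two-sided permutation tests gave p = 0.1 for 2i against primed cells, 0.3 for 25 µM against 2i, 0.1 for 50 µM against 2i and 0.5 between the doses, where 0.1 is the smallest p that 3 against 3 libraries allow. With same-numbered libraries taken as pairs, a test chosen after seeing the data, the index was higher than in 2i in 3 of 3 pairs at 25 µM and in 3 of 3 at 50 µM. The exact two-sided paired permutation p was 0.25 for each, the smallest that 3 pairs allow, and 0.75 between the doses, where 2 of 3 pairs were higher at 50 µM. In the edgeR fits the mean log2 change of the naive list against 2i was −0.05 at 25 µM and −0.11 at 50 µM. That of the primed and formative list was −0.18 and −0.37. Both means were thus lower, that of the primed and formative list by more, and neither list was called. A wider measure used 1997 to 2124 genes that 2i changed by 2-fold or more, chosen with the 2i library used for the comparison left out, and asked how far the inhibitor moved them along the 2i response, whose median size was 1.71 on the log2 scale. The shift was −0.007 at 25 µM (−0.02 to 0.007 over the 3 held-out libraries) and −0.116 at 50 µM (−0.122 to −0.105), negative meaning back toward primed levels and positive further along the 2i response. At 25 µM, genes that had risen in 2i had −0.1 (−0.131 to −0.053) and genes that had fallen in 2i had 0.084 (0.078 to 0.095), opposite in sign. At 50 µM these were −0.351 (−0.371 to −0.318) and 0.09 (0.078 to 0.098).

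Of the 1067 genes lower at 50 µM than in 2i, 488 had risen in 2i against primed cells, where independent lists give 214 and simulated unchanged groups 0.1. Of the 927 genes higher at 50 µM, 309 had fallen in 2i (189 and 0.4). The other pairs of directions shared 111 genes that rose in both (186 and 0.05) and 189 that fell in both (217 and 0). Under the block, fitted in both comparisons, these 4 counts were 772, 535, 242 and 330, against 386, 384, 376 and 394 for independent lists. The simulated groups leave out the effects, so their overlaps near 0 do not measure what shared controls add. These comparisons share the 2i libraries with opposite sign, so part of the excess may come from the shared controls. The comparison of the doses uses none of those libraries, and there 79 of the 129 genes lower at 50 than at 25 µM had risen in 2i (25.8 for independent lists) and 18 of the 24 higher had fallen in 2i (4.89). Under the block these were 240 of 374 (88.1 for independent lists) and 87 of 168 (40.4). Without the block, the other pairs of directions shared 22 genes that fell in both (26.3) and 1 that rose in both (4.81). The independent counts take no account of expression level, which affects how readily a gene is called in either comparison, so they are a reference and not a test.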

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

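Of the settings given here, the tests with replicates 2 and 3 only and with the index in pairs were chosen after seeing the data; the others were planned. No named gene with a call changed direction under the settings run for it. Of values without a call, the median of ribosome biogenesis factors at 25 µM went from 0.01 to −0.01 with size factors, and the 25 µM shift changed sign as given below. Requiring a log2 change of at least 1 left 2128 genes in 2i against primed, 37 at 25 µM against 2i, 619 at 50 µM against 2i, 53 between the doses, and 2194 and 2236 at 25 and 50 µM against primed, by construction. Without a low-count filter, 268 genes were called at 25 µM and 329 between the doses; the cause was not tested. DESeq2 called 4928, 161, 1730 and 207 genes and limma voom 5307, 108, 1900 and 119 in 2i against primed, 25 µM, 50 µM and between the doses, all within 1.5 times the edgeR counts, as were the counts with size factors, with the CPM filter and with only the compared groups. Leaving out 1 library gave 4615 to 4991, 29 to 101, 1217 to 1668 and 38 to 203 genes in the same order, and 4926 to 5297 and 5117 to 5486 for the doses against primed; such fits have fewer libraries. Replicates 2 and 3 only gave 238 between the doses, the cause of which was not tested, and within 1.5 times elsewhere.

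With the replicate block, 627 genes were called at 25 µM, 3240 at 50 µM and 542 between the doses, and the shared count of 123 became 568. Against primed cells, where same-numbered libraries correlated by 0.09 or less in at least 1 pair, the numbers are not taken to pair the samples, and the block gave 6294, 6543 and 6786 for 2i, 25 and 50 µM. All 12 libraries correlated best on average with those of their own number, a hint from the data and not from the design. In 2i against primed the block also called fibroblast markers (0.0074, against 0.054; adjusted p = 0.24 with an estimated correlation and no block). Lists called numbered 9, 10, 11 and 12 with the block, against 8, 8, 12 and 10. For lists it changed no call other than these and those in the report.

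With an estimated correlation 3, 2, 2 and 0 lists were called, and fry, which does not compare a list with other genes, called 22, 4, 16 and 2. Leaving out 1 library gave 8 to 11, 8 to 9, 8 to 12 and 7 to 11 lists. The shift at 25 µM was −0.043 and that at 50 µM −0.159 with no 2i library held out, where the genes are chosen on the same libraries. It was −0.063 at 50 µM with no fold minimum, which adds genes with small responses. Without 1 library it was −0.019 to 0.007 at 25 µM, so its sign depends on 25 µM replicate 1 (0.007 without it), and −0.122 to −0.111 at 50 µM. The shared count was 35 with the fold minimum, 29 to 126 without 1 library and 136 in replicates 2 and 3. With a prior count of 0.5 the index differed by 3.26 between 2i and primed and by 0.26 between 50 µM and 2i, against 3.07 and 0.17; a smaller prior widens differences of low genes.

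Of 422 pairs of named gene and comparison, 236 were called. DESeq2 lost 2 calls and gained 14 over the 417 it gave a value for, limma voom lost 11, size factors lost 3 and gained 3, the block lost 0 and gained 62, the 2 groups alone lost 15 and gained 3 of 408, and replicates 2 and 3 lost 18 and gained 16. Calls lost without at least 1 library numbered 68, and 0 changed direction. The median log2 change of all genes was at most 0.029 in size. At this depth, genes with a few counts per library, such as those of the 2-cell-like state, have wide counting intervals.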

Other observations

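The tests chosen only after the result was seen are the 4 gene families of the first 3 paragraphs, the tests of an outlying library, of shared copies and of depth for the 2-cell-like genes, both tests of methyltransferase transcripts, the tests of germline genes by their 2i response, and the test of depth for replicate 1; the others were written before. Among replication-dependent histone genes, which package newly made DNA, calls at 50 µM went one way; no set test was run on this family. Of 42 measured, 22 rose and none fell at 50 µM against 2i (median log2 change 1.23, and 1.21 with DESeq2 size factors), and 21 rose by DESeq2 and 23 by limma voom. Hist1h2ae rose from 6.37 ± 1.47 to 26.9 ± 3.24 CPM (n = 3 per group), Hist1h3d by 2.05 ± 0.29 and Hist1h1c by 1.02 ± 0.17. At 25 µM 4 rose, with a median of 0.63, and 2 without 2i replicate 2, 25 µM replicate 1 or 25 µM replicate 2. In 2i against primed cells 20 fell and none rose (median −0.87), 13 without primed replicate 3 and 10 without 2i replicate 2. Most histone mRNAs lack the poly(A) tail that the kit primes on, and the genes are near-identical copies, so the level of any one is uncertain.

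Some genes of betaine, methionine and cysteine metabolism rose in 2i and fell at 50 µM, among them Bhmt and Cbs; no set test was run on this family either. Of 11 measured, 6 rose and 2 fell in 2i against primed cells, the 2 becoming 1 without any library but primed replicate 1. Bhmt, an enzyme that makes methionine from betaine, went from 0.264 ± 0.0826 to 16 ± 2.31 CPM, Dmgdh rose by 5.58 ± 0.30, and Cbs, which starts cysteine synthesis, by 1.21 ± 0.12. At 50 µM against 2i none rose and 4 fell (5 without 50 µM replicate 3), among them Bhmt (−1.58 ± 0.21) and Cbs (−1.10 ± 0.12), with the same counts under size factors.

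The other 2 families counted after the values were seen had no set test either. Of 76 cytosolic ribosomal protein genes other than Rpl13a, 23 rose and none fell at 50 µM against 2i (median 0.24), with 0 lower at an unadjusted edgeR p under 0.05. With size factors 20 rose (median 0.22), by DESeq2 22 and by limma voom 24, with no fall in any. The 23 became 15 without 2i replicate 2, 11 without 2i replicate 3, 9 without 50 µM replicate 1 and 13 without 50 µM replicate 3. Of 7 BMP target genes 2 rose and 1 fell, and 1 rose without any 1 of the 6 libraries.

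The 9 measured 2-cell-like genes were lower at 50 µM than in 2i alone. An outlying library is argued against, since the lowest summed level in 2i was 16.7 times the highest at 50 µM. Reads shared between copies are argued against as the whole cause by Sp110, Tmem92 and Arg2, so far as these have no near-identical copies. They lie outside the families set apart by name as multicopy, but copies of these genes were not looked for. Their log2 changes were −4.92, −5.27 and −2.99, so the median of −4.92 is that of Sp110. Lower depth is argued against by a mean library total at 50 µM of 0.993 times that in 2i. A hypothesis that stays open is that the inhibitor may lower the share of cells in this state or its transcripts per cell, which bulk counts do not separate.

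The germline genes were lower at 50 µM too. A return to the primed state is argued against for members that 2i had lowered, since over all 12 of these on the list, chosen by their call in 2i against primed cells alone, the median change at 50 µM against 2i was −0.69 (SE 0.14, from −1.54 to −0.28; 5 fell, 7 were not called), away from primed levels. It stays open for the 7 members that 2i raised and 50 µM lowered, whose median against primed cells was −0.18 (SE 0.56; 3 lower, 2 not called and 2, Dazl and Rpl10l, higher). The median of all 14 that fell, −1.21 against primed cells, decides nothing, as members already below primed in 2i had to lie below it. Higher de novo methyltransferase transcripts are argued against by a mean log2 change of −0.15 over Dnmt3a, Dnmt3b and Dnmt3l. Its 95% interval, built on the mean SE of the single genes, was −0.4 to 0.09. Transcripts of the maintenance factors Dnmt1 and Uhrf1 were higher by a mean of 0.46 (0.27 to 0.64, built likewise). Higher maintenance transcripts therefore stay open as an explanation, and that they act on the germline genes was not tested. The call of Dnmt1 alone (0.31 ± 0.10, edgeR adjusted p = 0.0423) was lost without 2i replicates 1 (0.118) or 2 (0.194) or 50 µM replicates 1 (0.106) or 3 (0.197), and DNA methylation itself was not analysed here.

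The replicate 1 libraries deviated together in all 4 groups, with a mean correlation of 0.239 against 0.112 for replicates 2 and 3. One abundant transcript took more counts there (ENSMUSG00000119584, 2.498 ± 0.173% of counts in replicate 1, n = 4 libraries, against 0.78 ± 0.107% and 0.9582 ± 0.194% in replicates 2 and 3). Leaving it out gave a correlation of 0.238, which decides nothing, since rescaling moves all other genes of a library alike and a correlation across genes does not register that. Depth is argued against, as replicate 1 was the deepest library in 1 group and the shallowest in 1, and so is gene length, with a Spearman rho across genes of 0.034 over 13065 genes (98.8% of those tested). GC content stays open, with a rho of −0.11, between the bounds set for and against it, and genes are not independent replicates. After that transcript, mt-Rnr2 (0.73) and mt-Rnr1 (0.67) had the highest replicate 1 deviations, chosen after their values were seen, and no biological explanation was tested.

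The 6 libraries of a comparison form 10 splits, too few for a share below 0.05. Every split other than the real one mixes libraries of both groups, so a real difference adds to the spread within its groups. Few or no gene calls in those splits are thus built in and decide nothing. The real split called 5346 genes in 2i against primed, 124 at 25 µM, 1994 at 50 µM, 153 between the doses, and 5594 and 5859 at 25 and 50 µM against primed, where the highest other split called 0; 1 split, the real one, gave as many in each. For lists, 3 splits gave as many as the real one in 2i against primed (8, highest other 9), 2 at 25 µM (8, highest other 8), 1 at 50 µM (12, highest other 8) and 1 between the doses (10, highest other 8).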
